A study of Xenopus laevis with 89 samples.

How the data were processed

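Gene expression was measured in the brains of Xenopus laevis tadpoles at Nieuwkoop and Faber stage 54, an early prometamorphic stage at which the tadpole begins to respond to rising thyroid hormone. The labels describe exposure to triiodothyronine (T3) at 5 concentrations (0.48 nM, 0.97 nM, 1.92 nM, 3.84 nM and 7.68 nM) or to thyroxine (T4) at 10, 20.1 and 40.3 nM, each set with its own control (LSW), and sampling after 24, 48 and 96 h. Each array carried RNA of 1 animal that was amplified and copied into cDNA labelled with radioactive phosphorus, hybridized to a spotted cDNA array with 1 label. There were 53 T3 arrays in 18 groups and 36 T4 arrays in 12 groups, with 3 arrays per group except for 1.92 nM T3 at 96 h, which had 2. Per the labels, each concentration had 2 exposure replicates and 2 animals were taken from each at each time, but which of them an array came from is not in the labels, so every p is over animals, and arrays of 1 group can share an exposure replicate. An inhibitor experiment that the labels also describe was not analysed here. For 12 T4 arrays the title gives 48 h and the source label 24 h; the title was used, and under it each set and time holds exactly 1 array with whole numbers only, 6 arrays in all.

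The deposited values are background-subtracted spot signals, in intensity on a linear scale, for 898 spots per array. The authors' background and scaling methods, software and spot filters are not given in the sources used here. Empty cells were taken as missing, from 8 to 138 spots per array, and between 214 and 602 spots per array held values at or below 0. Consecutive spots formed 449 probes of 2 spots each. The platform table gave a single gene symbol to 250 probes, covering 243 genes, and 199 probes have no gene name in the sources used here. Symbols were updated through the Entrez identifiers of the probe table, of which 240 were found in the annotation of the Xenopus laevis genome assembly, version 10.1, and positions are from that annotation. Per the labels, the authors selected genes at least 2-fold from control, removed genes whose spread, (maximum - minimum)/2, exceeded a limit of 1.1 to 1.7 that depended on the data set, and required at least 4 observations. The fold and this spread, at 1.1 and at 1.7, were run as an alternative on the normalized values; the number of observations was not applied.

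Values were taken to log2, with values at or below 0 left out. The medians of the arrays had an SD of 0.54, above the limit of 0.1 up to which the table would have been used as deposited, so the arrays were quantile normalized over all 89. Duplicate spots were averaged on the log2 scale. The noise of an array was the root mean square of its values below 0, from 152 to 2063 intensity units, and a probe counted as above background on an array where the mean of its duplicate spots exceeded 2 times that noise. The number of arrays per group limits the precision of every value.

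A linear model with 30 group means was fitted to each probe over all 89 arrays, with the variance moderated as in limma 3.58.1 under R 4.3.3. Each probe was fitted exactly, with the design of the arrays on which it has a value, so that missing values do not distort the standard errors of contrasts. The fit was checked against limma's own on the 28 measured probes with a value on every array. A probe was tested where each group of a contrast had at least 2 values. The dose trend at each time is a linear contrast over the order of the doses, with control as step 0, so that a slope is in log2 per dose step. Further contrasts set each dose against the control of its set and time, the response to 10 nM T4 against the response to 7.68 nM T3 at each time, and the response to the highest dose at 96 h against that at 24 h. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the probes of a trend, or over all probes, doses and times of a set for the single doses, with a threshold of 0.05. Errors of differences and slopes are standard errors of the fit and intervals are at 95%. Treated arrays above the control mean are counted out of the treated arrays with a value, so arrays without one are left out. Where all arrays of exactly 1 of the compared groups lay at or under background, the fold is given against a floor. Each such array was set to the larger of its value and the lowest normalized signal above background on it. An array without a value was set to that signal. In the other group, an array without a value was left out of the mean. Such a fold can therefore exceed the fitted difference or differ from it in direction. Spots were averaged on the log2 scale for the signal but on the linear scale for the background call. This floor can therefore lie below 2 times the noise. A fold given as "at least" is relative to this floor, carries no standard error and is not a strict lower bound. Where both groups lay at or under background, or a group had no value at all, no fold is given.

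The comparisons, the alternatives, the rule for named genes and 16 gene lists were fixed before the data were examined. The lists cover thyroid hormone receptors and direct response genes, thyroid axis genes, nuclear receptors and cofactors, cell cycle and DNA replication, apoptosis, extracellular matrix and matrix proteases, neuronal and synaptic genes, glia and myelin, heat shock and protein folding, ribosome and translation, energy metabolism, and markers of blood, muscle, liver, skin and immune cells. Genes were named by this rule: at each set and time the 5 largest rises and the 5 largest falls among the probes past the threshold or, where fewer than 3 passed, the 5 with the smallest p, given as values; every measured member of the thyroid hormone response list; and the 5 with the smallest p in the contrast of T4 with T3 and in those of 96 h with 24 h. The rule does not cover the single doses, the F test, the genes above background or the other lists, where names were chosen after the values were seen. Probes without a gene name were counted, and at most 2 that rose and 2 that fell are identified by number. Lists with at least 3 tested genes at a time were tested on the dose trend with camera of limma on the moderated statistics, with a preset correlation of 0.01, and again with a correlation estimated from the residuals of the list's genes. Each gene counted once, by the mean of its probes. The directional test fry was run where at least 3 genes of a list had values on all arrays of the set and time. A further list of genes first cloned as thyroid hormone responsive in tadpoles was added after the gene names were seen.

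The number of probes above background per array was compared over the dose order with a two-sided permutation test of 100000 resamples within each time. Alternatives to the normalization, the filter on dim probes, the treatment of missing values, the arrays in the fit, the replicate number as a block, the variance model, array weights, the test over doses, the dose scale, the adjustment and the selection rule were run, each array was left out in turn, and 5 further alternatives were added after seeing the data, as was a dose trend averaged over the 3 times. These 5 raised values under the noise of their array to it, did so and tested only probes above background in a group, averaged duplicate spots before the log2, left out the 7 arrays with more than 150 values of exactly 0, or took the log2 number of probes above background as a covariate. The control arrays of the T3 and T4 sets were compared with each other within times. For each count, the arrays were regrouped at random within their set and time 100 times, the real grouping included. The fit was also tested on simulated data. In each of 20 simulations, 8 probes per trend changed at each fold of 2, 4, 8, 16 and 32 at once. The noise was normal and independent, with the measured variance of each probe, and the real missing values were kept. Trends of 16-fold at the highest dose were recovered for 64.4% to 81.9% of the changed probes. Trends of 4-fold were recovered for 10% to 23.8%, and trends of 2-fold for 0.625% to 6.25%. Between 2.07% and 5.58% of the calls were false. These rates hold for that setting and can differ where few probes change, where low signals go missing or where arrays vary together. Probe tables and figures were made under Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.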

Results

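The brain of the tadpole was profiled during exposure to T3, the form of thyroid hormone that binds its receptors most strongly, or to T4, which carries 1 iodine more and serves as its precursor. The labels place the series within an assay of metamorphosis for disruption of the thyroid axis, and state that animals exposed to either hormone metamorphosed faster. The T3 set held 53 arrays in 18 groups and the T4 set 36 arrays in 12 groups, with 3 arrays per group except for 1.92 nM T3 at 96 h, which had 2. Of 449 probes, 8 were above background on all 89 arrays and 66 on at least 45 arrays. The named genes among those 8 were casp1.L, a caspase of inflammation, katna1.S, the catalytic subunit of the microtubule-severing protein katanin, ldhb.S, a lactate dehydrogenase subunit, and npr3.L, the clearance receptor for natriuretic peptides. Further genes, chosen with these after their values were seen, were above background on many arrays: gapdh.S on 87 arrays, ccnd2.L on 85, the corticotropin-releasing hormone receptor crhr2.S on 84, neuropeptide Y (npy.S) on 83, the prohormone convertase pcsk2.L on 83 and growth hormone (gh1.S) on 69. Prolactin (prl.1.L) was above background on 24 arrays, and thyrotropin-releasing hormone (trh.S) on 14, named likewise.

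The T3 arrays had a median of 150 probes above background, with a range of 46 to 220, and the T4 arrays a median of 68.5, with a range of 23 to 108. Within the T4 set the number differed with dose. It averaged 85.4 ± 17.2 in controls, 73.9 ± 25.8 at 10 nM, 48.6 ± 24.5 at 20.1 nM and 58 ± 20.4 at 40.3 nM (SD, 9 arrays each). The slope was -10.8 probes per dose step, with p = 0.00441 in the permutation test. Within the T3 set the slope was 3.75 probes per dose step, with p = 0.220 in the permutation test.

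**Figure D1:**
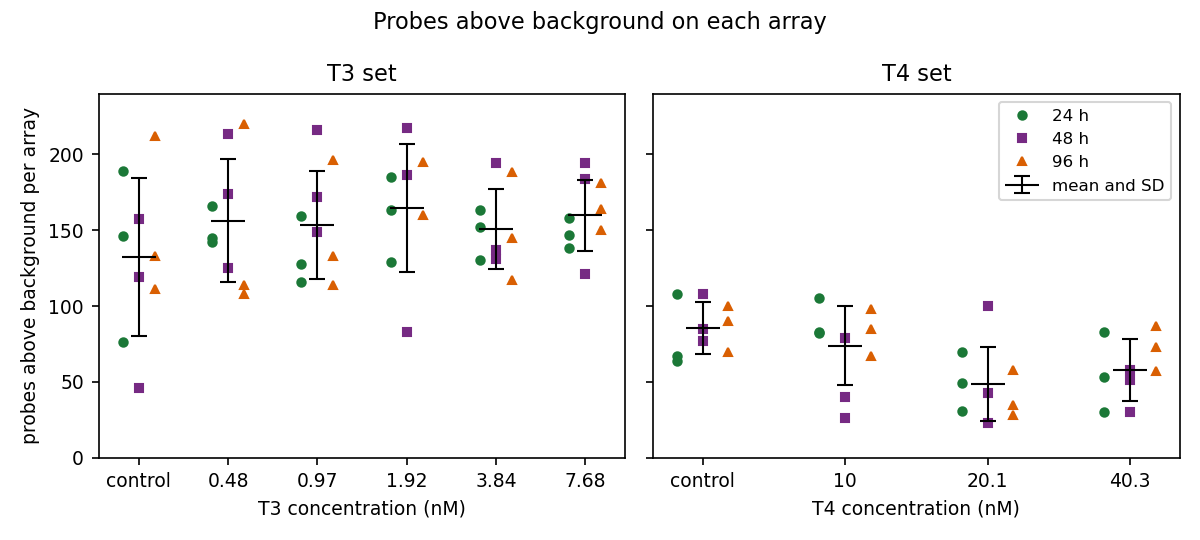
Number of probes above background (vertical axis) on each array against the T3 or T4 concentration in nM (horizontal axis, dose order); symbols mark 24, 48 and 96 h, and bars give the mean and SD per dose. T4 controls average 85.4 probes and T4 arrays at 20.1 nM average 48.6.

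The first question was whether brain transcripts followed the T3 dose at 24, 48 or 96 h. No named gene and no probe without a name passed the test for a trend at any of these times: limma called 0 of 196 probes at 24 h, 0 of 206 at 48 h and 0 of 188 at 96 h. At an unadjusted p under 0.05 there were 9, 5 and 8 probes, and the F test over the doses called 0 at each time. The gene with the steepest slope among the named genes was rxrb.L at 96 h, the retinoid X receptor beta, a partner that thyroid hormone receptors bind to on DNA, located on chromosome 8L from 64029617 to 64045145. Its slope was -0.97 ± 0.30 log2 per dose step (adjusted p = 0.201). Its mean log2 signal was 10.90 ± 0.25 in controls (SD, n = 3), with all 3 arrays above background. At 7.68 nM it was 5.42 ± 1.89 (SD, n = 2), with 0 of 3 arrays above background. Relative to the floor described above, the signal was at least 12.6-fold lower, which is not a strict bound. Of the 11 treated arrays with a value at 96 h, 1 lay above the control mean. At 48 h its slope was 0.40 ± 0.30 (adjusted p = 0.927). The trend of rxrb.L at 96 h passed the threshold with each array centred on its median (slope -1.26, adjusted p = 0.00456) and with the replicate number as a block (adjusted p = 0.0466). With values under the noise raised to it the slope was -0.22, and over the alternatives the adjusted p lay between 0.00456 and 0.598.

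At 96 h, xepsin.L, a serine protease encoded on chromosome 9_10L from 130183116 to 130190332, had a slope of -0.83 ± 0.24 (adjusted p = 0.201). It was above background on all 3 controls and on 0 of 3 arrays at 7.68 nM, a signal at least 7.26-fold lower, and 1 of 11 treated arrays lay above the control mean. With values under the noise raised to it the slope of xepsin.L was -0.29 (adjusted p = 0.0377), and over the alternatives its adjusted p lay between 0.0235 and 0.501. The homeobox factor crx.L had a slope of -0.75 ± 0.28 at 96 h (adjusted p = 0.522), with no array above background in either the controls or the 7.68 nM group and 2 of 12 treated arrays above the control mean. The remaining 2 of the 5 smallest p at 96 h belonged to probes without a gene name. At 24 h, the adenosine A1 receptor adora1.L had a slope of -0.48 ± 0.16 (adjusted p = 0.581) and was at least 3.30-fold lower at 7.68 nM, where 0 of 3 arrays were above background against all 3 controls, and 5 of 15 treated arrays lay above the control mean. The transcription factor nfib.L had a slope of 0.41 ± 0.18 at 24 h (adjusted p = 0.874), and 14 of 14 treated arrays with a value lay above the control mean, which rests on 2 values. Its slope was 0.07 ± 0.17 at 48 h (adjusted p = 0.927), -0.05 with each array centred on its median, and -0.12 ± 0.17 at 96 h (adjusted p = 0.938). At 48 h, the slope of DNA topoisomerase I (top1.1.L) was 0.60 ± 0.21 (adjusted p = 0.719), with a signal at least 4.64-fold higher at 7.68 nM than in controls. Of its treated arrays, 13 of the 13 with a value lay above the control mean, which rests on 2 values. The slope of the neuronal adhesion protein contactin 1 (cntn1.L) was 0.51 ± 0.23 (adjusted p = 0.927), with 10 of 14 treated arrays above the control mean. The other 3 of the 5 smallest p at 24 h and 3 of 5 at 48 h had no gene name. The standard error of the difference between the highest dose and control had a median of 1.32, 1.34 and 1.30 log2 at the 3 times.

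**Figure D2:**
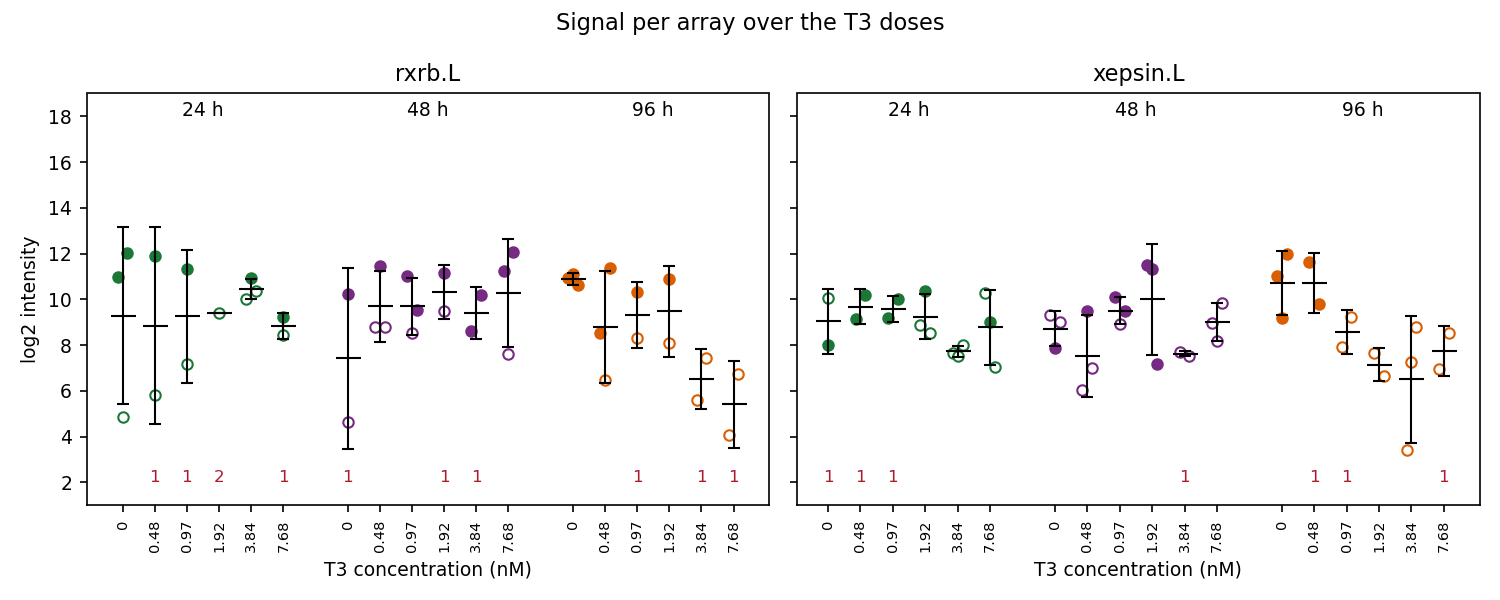
Log2 intensity (vertical axis) of rxrb.L and xepsin.L on each T3 array against the concentration in nM (horizontal axis, 0 is control) at 24, 48 and 96 h. Filled points are above background and open points are not, bars give mean and SD, and numbers at the bottom count arrays without a value; at 96 h all controls are filled and all arrays at 7.68 nM are open or without a value.

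The genes known to respond directly to thyroid hormone in tadpoles, with the receptor's partner, formed a list of 7 measured genes, and no probe on the array was named for the receptor genes thra and thrb. They were cebpa.L, nfib.L, nf1-c1, klf9.L, thibz.L, rxrb.L and fap.L. None of them had a trend past the threshold over all probes in either set. Over T3, the tested members had 3 positive and 1 negative slopes at 24 h under all 3 scalings, 3 positive and 0 negative at 48 h, where centring each array on its median gave 2 and 1, and 0 positive and 2 negative at 96 h. The camera test gave adjusted p = 0.930 at both 24 h and 48 h. Over T4, 4 of 4 tested members had positive slopes at 48 h, where both other scalings gave 3 of 4, and the camera test gave adjusted p = 0.567. At 24 h there were 1 positive and 2 negative slopes (adjusted p = 0.987) and at 96 h 2 positive and 2 negative (adjusted p = 0.836), under all 3 scalings. Signals were low for most of these genes. The Krüppel-like factor klf9.L, an immediate target of the thyroid hormone receptor, was above background on 2, 2 and 3 T3 arrays and 0, 0 and 1 T4 arrays at the 3 times and could not be tested for a trend in either set, because some groups had fewer than 2 values. At 96 h it was above background on 0 of 3 T3 controls and 1 of 3 arrays at 7.68 nM, with a mean of 9.59 ± 0.50 (SD, n = 3) at that dose.

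The bZip factor thibz.L, named for its induction by thyroid hormone, had a slope of 0.11 ± 0.21 over T3 at 24 h (adjusted p = 0.990), 0.03 ± 0.43 over T4 at 48 h (adjusted p = 0.965) and 0.94 ± 0.38 over T4 at 96 h (adjusted p = 0.594). In the last case 8 of 9 treated arrays lay above the control mean, but no control array and no array at 40.3 nM was above background. Over T3 at 48 and 96 h, where 4 arrays each were above background, and over T4 at 24 h, thibz.L could not be tested for a trend. The slope at T4 48 h turned to -0.12 with the array signal as a covariate, to -0.05 with the replicate number as a block and to -0.01 with array weights. For cebpa.L the T3 slope was -0.21 ± 0.27 at 24 h, 0.02 with values under the noise raised to it, and 0.26 ± 0.29 at 48 h. Its T4 slope was -0.53 ± 0.50 at 24 h and 0.90 ± 0.53 at 48 h, with 0 of 12 arrays above background at either time, and the value at 24 h became 0.01 with values under the noise raised to it. At 96 h cebpa.L could not be tested for a trend in either set. There its signal at 7.68 nM T3 was 10.6-fold higher relative to the floor, with 0 controls and 1 treated array above background. The fitted difference was smaller, 2.42 ± 1.71 log2 (5.35-fold, n = 2 each), so the 10.6-fold is not a lower bound. At 40.3 nM T4 its fitted difference from control was 0.06 ± 1.56 log2, while the floor gave a signal 1.02-fold lower. No direction can therefore be given (1 control and 0 treated arrays above background). The T3 slope of nf1-c1 at 24 h was 0.28 ± 0.29, and at 48 and 96 h it could not be tested for a trend over T3. Its T4 slopes were 0.83 ± 0.49, 0.23 ± 0.50 and 0.33 ± 0.50 at 24, 48 and 96 h, with at most 1 array above background at a time, and the value at 48 h turned to -0.13 with duplicate spots averaged before the log2. The T4 slopes of nfib.L were -0.34 ± 0.32, 0.09 ± 0.35 and -0.47 ± 0.35, and the value at 48 h turned negative with the values as deposited (-0.29) and with each array centred on its median (-0.05). Fibroblast activation protein (fap.L) was above background on 8, 9 and 9 T3 arrays at the 3 times, and its difference between 7.68 nM and control was 0.98 ± 1.75 log2 at 24 h and -1.96 ± 1.75 at 96 h. Over T4 it was above background on 2 of 3 controls at 24 h and at 48 h. No array at 40.3 nM had a value at these times, so no fold is given. Only 3 of 12 arrays at 24 h and 5 of 12 at 48 h had a value. At 96 h it was above background on 1 of 3 controls and 2 of 3 arrays at 40.3 nM. For rxrb.L the T4 slope at 96 h was -0.38 ± 0.51, and 0.03 with values under the noise raised to it. This gene could not be tested for a trend over T3 at 24 h or over T4 at 24 and 48 h.

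**Figure D3:**
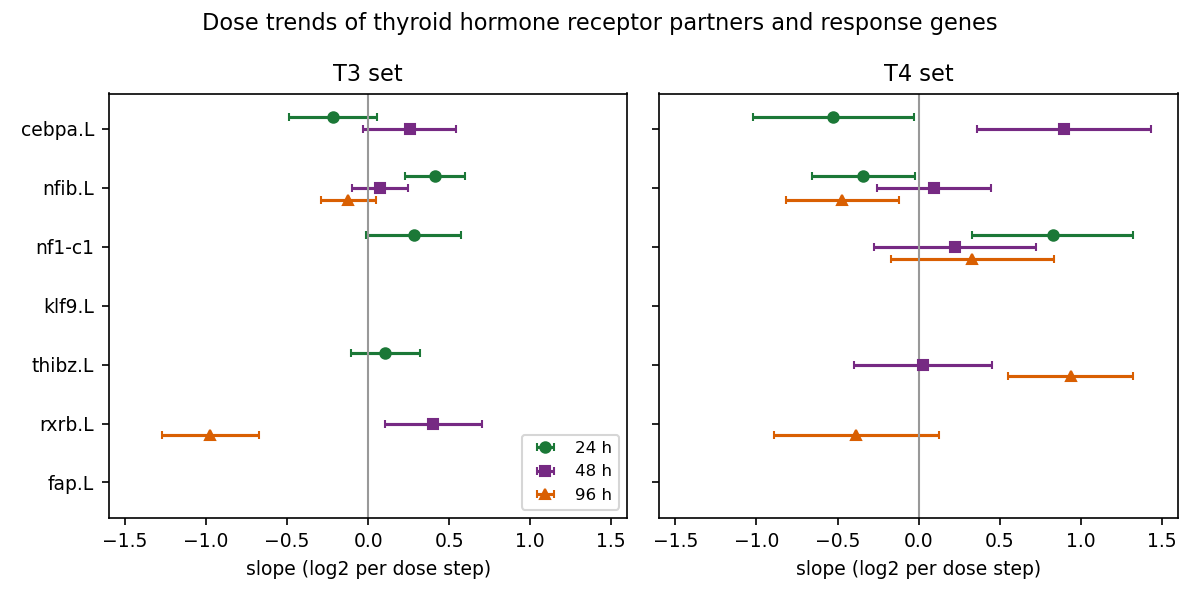
Slope in log2 per dose step (horizontal axis) of each measured thyroid hormone response gene (vertical axis) over the T3 or T4 doses at 24, 48 and 96 h; points are estimates and bars are standard errors. Slopes range from -0.97 for rxrb.L over T3 at 96 h to 0.94 for thibz.L over T4 at 96 h, and klf9.L and fap.L have no slope.

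Over all lists tested on T3, the thyroid hormone response list included, limma's camera called 0 of 21 list and time pairs, 0 pairs had an unadjusted p under 0.05, and the smallest adjusted p was 0.930. With an estimated correlation 0 pairs were called, and fry called 0 of the 3 pairs it could be run on; neither p of fry compares a list with other genes. Members of the other lists are given as examples, chosen after their values were seen. Where the scaling moved the median slope of all genes by more than 0.1 log2, it went over T3 from 0.03 and 0.01 to -0.08 and -0.12 at 48 and 96 h with each array centred on its median, and over T4 from -0.04, 0.04 and -0.01 to 0.10, -0.14 and -0.26 at 24, 48 and 96 h with the values as deposited. For thyroid axis genes, 4 members were tested at each time. Growth hormone (gh1.S) had slopes of -0.37 ± 0.20, 0.11 ± 0.19 and -0.36 ± 0.20 at 24, 48 and 96 h, and crhr2.S slopes of -0.03 ± 0.13, 0.03 ± 0.13 and -0.08 ± 0.13. In the cell cycle list 4 of 7 tested genes had positive slopes at 48 h, 3 of 7 with each array centred on its median and 5 of 7 with the values as deposited. At 24 h these numbers were 3, 2 and 3 of 5, and at 96 h 3, 0 and 3 of 6. Adjusted over the list alone, 1 gene passed at 48 h against 0 over all genes, top1.1.L (adjusted p = 0.0491). Cyclin D2 (ccnd2.L), which drives entry into the cycle, had a slope of 0.19 ± 0.11 at 48 h and -0.02 ± 0.11 at 96 h, and the mitotic kinase cdk1.S had -0.36 ± 0.18 at 96 h. In the list of nuclear receptors and cofactors, 3 of 5 tested genes had positive slopes at 24 h and at 48 h, 2 of 5 at both with each array centred on its median, and 1 of 4 tested genes had a positive slope at 96 h under all 3 scalings; adjusted over the list alone, 1 gene passed against 0 over all genes, rxrb.L (adjusted p = 0.00856). Neuronal genes included gap43.S, a growth cone protein, with a slope of 0.16 ± 0.26 at 96 h, and the tubulin tubb4b.L with -0.18 ± 0.17. The energy gene ldhb.S had slopes of 0.01 ± 0.10, -0.08 ± 0.10 and -0.06 ± 0.10 at the 3 times. The haemoglobin gene hbd.S, the marker of blood on the array, had slopes of 0.03 ± 0.16, -0.20 ± 0.16 and 0.29 ± 0.16. Median, mean and test differed in sign for nuclear receptors and thyroid axis genes at 24 h, for nuclear receptors, ribosome and energy at 48 h, and for cell cycle and ribosome at 96 h.

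The same question was asked of T4. A single probe without a gene name, number 1303, fell with T4 dose at 48 h, with a slope of -2.05 ± 0.47 log2 per dose step (adjusted p = 0.00878). Its mean signal was 13.69 ± 0.78 in controls and 6.95 ± 1.32 at 40.3 nM (SD, n = 3 each), at least 18.4-fold lower. All 3 controls and 0 of 3 arrays at 40.3 nM were above background, and 2 of 9 treated arrays lay above the control mean. Next by p was rpl35a.S, a protein of the large ribosomal subunit encoded on chromosome 5S from 87257087 to 87266350. Its slope at 48 h was -1.71 ± 0.48 (adjusted p = 0.0666), with means of 14.44 ± 0.25 in controls and 9.15 ± 2.91 at 40.3 nM (SD, n = 3 each), and 1 of 3 arrays above background at that dose. Of the treated arrays with a value, 4 of 8 lay above the control mean. It passed the threshold with the replicate number as a block (adjusted p = 0.0424) and with array weights (adjusted p = 0.00471), and over the alternatives its adjusted p lay between 0.00471 and 0.610. At 96 h its slope was -1.37 ± 0.47 (adjusted p = 0.594), with 4 of 9 treated arrays above the control mean. Its values on single arrays were spread widely: on the 3 arrays at 40.3 nM and 96 h they were 11.26, 15.54 and 8.09. The actin-binding tropomyosin tpm4.S had a slope of -1.24 ± 0.42 at 48 h (adjusted p = 0.183) and was at least 3.89-fold lower at 40.3 nM, with 2 of 8 treated arrays above the control mean. With values under the noise raised to it and only probes above background tested, its slope was -0.79 (adjusted p = 0.0473), within a range of 0.0473 to 0.875 over the alternatives.

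In all, limma called 0 of 202 probes at 24 h, 1 of 205 at 48 h and 0 of 214 at 96 h over T4, and 17, 11 and 13 probes had an unadjusted p under 0.05. Of the tested probes, only 70 at each time were above background on at least 2 arrays of any dose group. Over T3 these were 159, 175 and 155 of the tested probes, so most T4 tests were on signals near background. The F test over the doses called 1 probe at 24 h, 2 at 48 h and 0 at 96 h; these were npy2r.S, a neuropeptide Y receptor, at 24 h, and probe 1303 and the serotonin receptor htr1a.L at 48 h, with npy2r.S and htr1a.L chosen after their values were seen. The call of probe 1303 at 48 h stood beside fewer probes above background at the T4 doses (slope -10.8 probes per dose step over all 3 times). At 48 h alone their number averaged 90 in controls, 48.3 at 10 nM, 55.3 at 20.1 nM and 46.3 at 40.3 nM. The count of calls at 48 h went from 1 to 0 with each array centred on its median, with a fit on the T4 arrays alone or on the T4 arrays of 48 h alone, with duplicate spots averaged before the log2, with the array signal as a covariate, and without replicate 1 of the 48 h control.

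**Figure D4:**
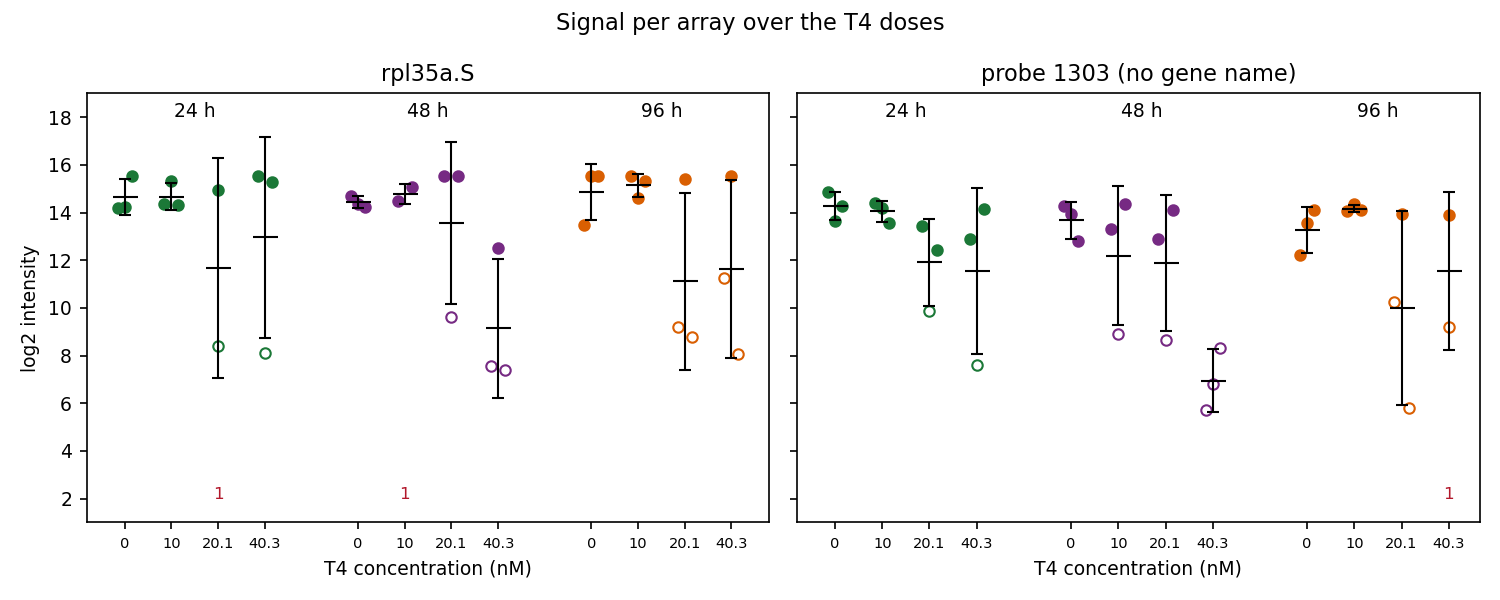
Log2 intensity (vertical axis) of rpl35a.S and of probe 1303 on each T4 array against the concentration in nM (horizontal axis, 0 is control) at 24, 48 and 96 h. Filled points are above background and open points are not, bars give mean and SD, and numbers at the bottom count arrays without a value; at 48 h and 40.3 nM the 3 values of probe 1303 average 6.95 against 13.69 in controls.

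At 24 h over T4, the natriuretic peptide receptor npr2.L had a slope of 1.30 ± 0.39 (adjusted p = 0.397), with no array above background in the controls or at 40.3 nM. All 7 treated arrays with a value lay above the control mean, which rests on 2 values with an SD of 3.09. The kinase pak1.S had a slope of 1.22 ± 0.44 (adjusted p = 0.545), with a signal at least 1.04-fold higher at 40.3 nM and 7 of 7 treated arrays with a value above the control mean. The other 3 of the 5 smallest p at 24 h, 3 at 48 h and 2 at 96 h belonged to probes without a gene name. At 96 h the slope of cdc7.L, a kinase needed for DNA replication to start, encoded on chromosome 4L from 100905801 to 100933024, was 1.37 ± 0.48 (adjusted p = 0.594). Its signal at 40.3 nM was 11.07 ± 0.78 (SD, n = 3) against 6.76 ± 1.04 (SD, n = 2) in controls, at least 4.61-fold higher, and 9 of 9 treated arrays lay above the control mean. With values under the noise raised to it in place of being left out, the slope of cdc7.L was 0.51 (adjusted p = 0.000793), and over the alternatives its adjusted p lay between 0.00018 and 0.898.

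Of the gene lists over T4, 9 could be tested, in 23 list and time pairs. The camera test called 0 of them, and 3 had an unadjusted p under 0.05, with a smallest adjusted p of 0.142. With an estimated correlation 0 pairs were called, and fry called 0 of the 4 pairs it could be run on. The ribosome and translation list had 0 positive and 3 negative slopes at each of the 3 times under all 3 scalings, with camera adjusted p of 0.344, 0.142 and 0.328 at 24, 48 and 96 h; with an estimated correlation the adjusted p was 0.266 at 48 h. Its members were rpl35a.S, rpl8.S, another large subunit protein, and the poly(A)-binding protein pabpc1.S. Adjusted over the list alone, 1 gene passed at each of the later times against 0 over all genes, rpl35a.S at 48 h (adjusted p = 0.00195) and at 96 h (adjusted p = 0.0147). The slope of rpl8.S was -0.42 ± 0.25, -0.24 ± 0.25 and -0.25 ± 0.25 at the 3 times. The array held 5 probes for rpl8.S, and at 48 h their slopes lay between -0.28 and -0.18. Each was above background on at most 2 of the 36 T4 arrays, so they are slopes of signals near background. These slopes, too, stand beside the fewer probes above background at the higher T4 doses.

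The energy metabolism list had 1 positive and 3 negative slopes at 24 h, 2 and 2 under the other scalings (adjusted p = 0.836). It had 4 positive and 0 negative slopes at 48 h and at 96 h, with camera adjusted p of 0.408 and 0.328; with the values as deposited there were 2 positive and 2 negative at 48 h and 1 positive and 3 negative at 96 h. Its genes were gapdh.S, ldha.L, ldhb.S and pkm.S, with slopes at 96 h of 0.27 ± 0.23, 0.27 ± 0.27, 0.24 ± 0.19 and 0.29 ± 0.38. Nuclear receptors and cofactors had 3 positive and 1 negative slopes at 24 h under all 3 scalings (adjusted p = 0.344) and 2 and 3 at 48 h, 1 and 4 with the values as deposited (adjusted p = 0.836). They had 4 positive and 4 negative slopes at 96 h, 3 and 5 with the values as deposited (adjusted p = 0.836), among them nr2f1.L with 0.65 ± 0.36. Of 6 cell cycle genes tested at 24 h, 5 had positive slopes, 4 with each array centred on its median (adjusted p = 0.716). Of 4 tested at 48 h all did, 3 with each array centred on its median and 2 with the values as deposited (adjusted p = 0.408). Of 7 cell cycle genes tested at 96 h, 4 had positive slopes, 3 with the values as deposited (adjusted p = 0.489), including ccnd2.L with 0.32 ± 0.22. Among thyroid axis genes, the thyroid transcription factor pax8.L, above background on 3 T4 arrays, had a slope of 0.75 ± 0.36 at 48 h and gh1.S had -0.27 ± 0.36, -0.36 ± 0.40 and -0.20 ± 0.36 at the 3 times, and the list's adjusted p lay between 0.567 and 0.987. Of 3 apoptosis genes tested at 24 h, 2 had positive slopes under all 3 scalings (adjusted p = 0.489); casp2.L, with 0.97 ± 0.47, was above background on 0 of the 36 T4 arrays. The neuronal list had adjusted p between 0.918 and 0.987. Of 3 extracellular matrix genes tested at 48 h, 1 had a positive slope under all 3 scalings (adjusted p = 0.987); collagen col2a1.L had -0.75 ± 0.44 at 24 h. Median, mean and test differed in sign for thyroid axis, neuronal and energy genes at 24 h, for extracellular matrix and neuronal genes at 48 h, and for thyroid hormone response genes and nuclear receptors at 96 h.

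The remaining lists had too few genes on the array for a test. Glia and myelin had 2, with slopes at T4 48 h of -0.33 ± 0.48 for the glutamine synthetase gene glul.L and -0.11 ± 0.42 for the myelin gene mbp.S. These were above background on 6 and 4 T4 arrays. Heat shock and protein folding had the chaperonin gene cct3.S alone, with a slope of -0.71 ± 0.35 over T4 at 96 h and of -0.04 ± 0.19 over T3 at 96 h. Blood had hbd.S, with T4 slopes of -0.14 ± 0.30, -0.19 ± 0.30 and -0.01 ± 0.30. Immune cells had the cytokine gene il1b.S, with T4 slopes of 0.16 ± 0.46, 0.44 ± 0.46 and 0.58 ± 0.42. It was above background on 3 T4 arrays. The muscle gene myf5.L had too few values for a trend, and 0 skin genes were on the array. The liver gene ambp.L had T4 slopes of 0.05 ± 0.45 at 24 h and 0.66 ± 0.40 at 96 h, and was above background on 1 T4 array. A list of genes first cloned as thyroid hormone responsive was added after the gene names were seen. Its camera p was 0.742 over T3 at 48 h and 0.276 over T4 at 96 h.

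Each dose was also set against its own control, and the genes named for this comparison were chosen after their values were seen. Over T3, limma called 0 of 4561 tests, with 173 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. The smallest p belonged to tbx2.L, a T-box transcription factor, at 0.97 nM and 48 h, where no array of either group was above background, and to adora1.L at 7.68 nM and 24 h, at least 3.30-fold lower, and at 3.84 nM and 96 h, at least 4.58-fold lower, with 2 further values from a probe without a gene name. Over T4, limma called 0 of 2545 tests, with 150 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0604, which belonged to probe 1303 at 40.3 nM and 48 h. The serotonin receptor htr1a.L was at least 3.58-fold higher than in controls at 10 nM and 48 h (adjusted p = 0.0717), with 0 of 3 controls and 1 of 3 treated arrays above background. At 20.1 nM it had a mean of 9.24 ± 1.59 and at 40.3 nM 7.46 ± 0.44 (SD, n = 2 each), against 5.98 ± 1.04 in controls (SD, n = 3). The difference of rpl35a.S at 40.3 nM and 48 h was -5.29 ± 1.49 (adjusted p = 0.455), and the netrin receptor gene dcc.L had 0 arrays above background in either group at 10 nM and 48 h.

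T3 and T4 differ by 1 iodine atom, and their concentrations did not overlap, so the responses to 7.68 nM T3 and 10 nM T4, the nearest pair, were compared, each against its own control. No probe passed the test for a difference between the hormones, which does not show that they acted alike, and the doses themselves differ: limma called 0 of 705 tests, 31 had an unadjusted p under 0.05, and the smallest adjusted p was 0.592. The precision was low, with a median standard error of 1.93 log2 for the difference between responses. At 24 h, adora1.L was 0.94 ± 0.97 log2 from control under T4 and at least 3.30-fold lower under T3. The fitted interval of the difference, 1.63 to 7.11 log2, takes the T3 signals under background as measured. At 96 h, rxrb.L was at least 12.6-fold lower under T3, while under T4 it was above background on 1 of 3 controls and 0 of 3 arrays at 10 nM. Its fitted interval, 2.54 to 12.6 log2, takes the signals under background in the T3 and T4 groups as measured. At 48 h, the corticotropin-releasing hormone receptor crhr1.2.S had the smallest p, with no array above background in any of the 4 groups, so no difference is given. The other 2 of the 5 smallest p had no gene name. All 3 genes had an adjusted p of 0.592.

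The last comparison asked whether the response to the highest dose differed between 96 h and 24 h. Over T3, limma called 0 of 254 probes, with 12 at an unadjusted p under 0.05 and a smallest adjusted p of 0.921. The maintenance DNA methyltransferase dnmt1.L was 1.33 ± 1.14 log2 from control at 24 h and at least 3.91-fold lower at 96 h, and the other 4 of the 5 smallest p had no gene name. Over T4, limma called 0 of 223 probes, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.908. Prolactin (prl.1.L) was 2.24 ± 1.40 log2 from control at 96 h, and at 24 h no array of either group was above background. The apelin receptor aplnr.L was at least 3.29-fold higher at 24 h, and at 96 h no array of either group was above background. For pak1.S the signal was at least 1.04-fold higher at 24 h and at least 1.74-fold lower at 96 h. For casp2.L no control array and no array at 40.3 nM was above background at either time, and for npr2.L that held at 24 h, while at 96 h it was at least 1.14-fold lower.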

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

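The alternatives that raised values under the noise, tested only probes above background, averaged duplicate spots before the log2, left out arrays with many exact zeros or took the array signal as a covariate were chosen after seeing the data. The count of calls for T4 against T3, for 96 h against 24 h in each set and for the gene lists stayed at 0 under every alternative run for them other than leaving out arrays. Signal over background limits what can be given as a fold: 88 of the 449 probes were above background on no T4 array.

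For the T4 trend at 48 h, with 1 call, the count was 0 with each array centred on its median, with a fit on the same set, with a fit on the same set and time, with duplicate spots averaged before the log2 and with the array signal as a covariate. The count was 2 with only probes that have a value on all arrays, with the replicate block, with a variance trend and robust fit, with the F test and with dose in nM. It was 3 with array weights and 7 with values under the noise raised to it and only probes above background tested. The T3 trend at 96 h gave 1 call with each array centred on its median, with the replicate block and with values under the noise raised to it, with or without the filter on background. The T3 trend at 48 h gave 3 with values under the noise raised to it, with or without that filter. The T4 trend at 24 h gave 1 by the F test and 2 with values under the noise raised to it. That at 96 h gave 1 with the latter and 6 with the filter added. Single T4 doses gave 2 calls without the dimmest 25% of probes, 1 with only probes that have a value on all arrays, 2 with the replicate block, 2 with a variance trend and robust fit. They gave 3 with array weights, 3 when adjusted within each dose and time, 4 with values under the noise raised to it and 2 with the filter added. Within T3, 45 of 53 arrays were closest to arrays of their own replicate number, with a mean correlation of 0.168 within numbers. The mean between numbers, -0.083, is no separate evidence, because values were centred within each group. Within T4, 12 of 36 arrays were closest to arrays of their own number. Of 130 pairs of T3 arrays with the same number, 94 had a correlation over 0.1, and the lowest was -0.246. The fit without the block leaves this likeness of T3 arrays in its spread. The labels do not say what the numbers stand for, so the block is a hint only. It was not run for 96 h against 24 h.

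The authors' rule on fold and spread has no test. At each time it was run on the normalized values of the highest dose against control, so its counts do not cover the other doses. At limits of 1.1 and 1.7 it selected 27 and 63 probes for T3 at 24 h, 37 and 81 at 48 h, and 38 and 99 at 96 h. It selected 37 and 80 for T4 at 24 h, 43 and 89 at 48 h, and 35 and 64 at 96 h. Over all doses and times, each dose against its control, it gave 493 and 1096 over T3, and 370 and 705 over T4.

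With each array left out in turn, the T4 trend at 48 h gave 0 to 3 calls: 0 without replicate 1 of the control, 3 without replicate 1 of 20.1 nM and 2 without its replicate 2. The T4 trend at 96 h gave 0 to 1, with 1 without replicate 2 of 40.3 nM. Single T4 doses gave 0 to 4: 4 without replicate 1 of 20.1 nM at 96 h, 2 without replicate 1 of 10 nM at 48 h or replicates 1 or 2 of 40.3 nM at 96 h, and 1 without replicates 2 or 3 of 40.3 nM at 24 h, replicate 2 of 10 nM or 3 of 20.1 nM at 48 h, or replicate 3 of 20.1 nM at 96 h. T3 gene lists gave 0 to 1, with 1 without replicate 1 of 0.48 nM at 48 h, and the other counts stayed at 0. Where 1 of the 2 arrays of 1.92 nM T3 at 96 h is left out, the lone array is assumed to vary like the other groups.

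Of 358 alternative values for 31 slopes of named genes, 337 kept their direction and side of the threshold, 9 passed it and 12 turned their sign. Of those that turned, nfib.L did so over T4 at 48 h (-0.29 as deposited, -0.0514 centred, -0.0543 with values under the noise raised to it) and over T3 at 48 h (-0.0475 centred). The others were thibz.L over T4 at 48 h (-0.0546 with the block, -0.0115 with weights, -0.12 with the covariate) and over T3 at 24 h (-0.0025 without the arrays with many zeros). Further ones were cebpa.L at 24 h with values under the noise raised to it (0.0224 over T3, 0.00805 over T4), rxrb.L over T4 at 96 h likewise (0.0279), and nf1-c1 over T4 at 48 h (-0.13 with duplicates averaged before the log2). For each change of count or sign, the cause was not tested.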

Other observations

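The dose trend averaged over the 3 times, its lists and scalings, and the tests of its falls against the normalization and against T3 were chosen only after the result was seen.

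The genes above background on all arrays gave these averaged slopes over T3: casp1.L -0.01 ± 0.03, katna1.S 0.05 ± 0.04, ldhb.S -0.04 ± 0.05 and npr3.L -0.03 ± 0.03 log2 per dose step. With each array centred on its median they were -0.16 ± 0.04 (adjusted p = 0.0104), -0.10 ± 0.05 (adjusted p = 0.159), -0.20 ± 0.05 (adjusted p = 0.0104) and -0.18 ± 0.05 (adjusted p = 0.0104), while the median of all probes went from -0.01 to -0.12. Over T4, quantile normalized, they were -0.14 ± 0.06 (adjusted p = 0.125), 0.12 ± 0.08 (adjusted p = 0.366), 0.28 ± 0.09 (adjusted p = 0.0527) and -0.03 ± 0.06 (adjusted p = 0.853). Over T3 limma called 0 of 99 averaged trends, with 6 at an unadjusted p under 0.05, and 0 with the values as deposited, but 14 with each array centred on its median, all of them falls. Over T4, 7 of 109 fell and 0 rose, with 25 at an unadjusted p under 0.05. With each array centred on its median 7 fell, and with the values as deposited 23, where the median of all probes was -0.22 against -0.07. The named ones that fell were rpl35a.S, with -1.29 ± 0.27 (adjusted p = 0.000792), and tpm4.S, with -0.81 ± 0.24 (adjusted p = 0.0306). Averaged over the times, the T4 slopes of the ribosome list were 0 positive and 3 negative, those of nuclear receptors 4 and 0, and those of energy metabolism 4 and 0, or 2 and 2 with the values as deposited. Camera gave unadjusted p of 0.0238, 0.0273 and 0.0161 for these lists, and an adjusted p of 0.0546 for each. Of the nuclear receptors and cofactors, vdr.S was above background on 1 of the 36 T4 arrays, nr3c1.L on 3, ncoa2.S on 10 and nr2f1.L on 18. The slopes of vdr.S and nr3c1.L are therefore those of signals near background.

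The 7 averaged falls over T4 coincide with fewer probes above background, and with the number of these as a covariate the median slope went from -0.81 to -0.61, a share of 0.762, while single probes kept from 0.334 to 0.812 of their slope, with a median of 0.560. The median standard error was 0.24 before and 0.25 after, and with the smaller slopes 0 of the 7 were called. Array signal and a response to T4 cannot be told apart here, because signal and dose move together. With the values as deposited 7 of them were also called, and 6 with each array centred on its median. The calls therefore did not rest on quantile normalization alone. Both scalings moved the median T4 slope of all probes down, from -0.07 to -0.22 and to -0.12. They lean towards falls, so they do not exclude the scaling as a cause. Over T3 the same probes had a median slope of -0.0329, and 0 of 6 lay more than 2 standard errors below 0. With each array centred on its median 1 of 6 did (median slope -0.16, all probes -0.12). The T3 concentrations and arrays differed from those of T4, so these slopes cannot decide on a response shared with T3. Chance cannot be excluded, since 5 of 100 regroupings gave as many calls, with 7 real and a highest other of 13. Leaving out single arrays gave 2 to 19 calls: 16, 3 and 19 without replicates 1, 2 and 3 of 40.3 nM at 24 h, 14 without replicate 1 of 20.1 nM at 48 h, 12 without replicate 1 of 20.1 nM at 96 h, and 2 and 4 without replicates 1 and 3 of 40.3 nM at 96 h.

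The control arrays of the T4 and T3 sets, 9 each, differed in 4 of 188 probes, 2 of which are also among the 7 averaged falls over T4. Higher in the T4 controls were the chromatin protein gene hmgn3.L, by 2.56 ± 0.52 log2 (adjusted p = 0.00933) and chosen after its value was seen, and 1 probe without a gene name. Lower were 2 probes without a gene name: number 1033 by 4.16 ± 0.31 log2 (adjusted p = 6.06e-08), and 1285 (adjusted p = 2.88e-05), which was above background on 9 of 9 T3 controls and 0 of 9 T4 controls. Of 100 regroupings 1, the real one, gave as many, with a highest other of 3. This makes chance unlikely but does not exclude it, since only 100 regroupings were run and they do not keep the replicate number. A set run apart from the other and a difference between the animals of the sets cannot be told apart for these 4 probes, because each set has its own arrays, and the animals were not compared otherwise.

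For the call over T4 at 48 h chance cannot be excluded: 13 of 100 regroupings gave as many calls, with 1 real and a highest other of 20. The regrouping with 20 calls may point to a structure of the samples that is not the dose or to probes that vary together, which was not tested. Among these 12 arrays, 3 were closest to arrays of their own replicate number, whereas T3 arrays of the same number were alike, which the regroupings do not keep. Where 0 calls were made, all 100 regroupings give as many by construction, which says nothing of chance. The highest other was 4, 5 and 2 for the T3 trend at 24, 48 and 96 h, 3 for the T4 trend at 24 h and 3 at 96 h, 8 for single T3 doses and 8 for single T4 doses, 4 for T4 against T3, 3 and 11 for 96 h against 24 h over T3 and T4, 3 and 1 for the T3 and T4 gene lists, and 7 for the averaged T3 trend.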
